A study of Mus musculus with 6 samples.

How the data were processed

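Cortex was taken from wild-type C57BL/6 mice, an inbred laboratory strain, in 2 groups: normal cortex (control, 3 libraries) and cortex around the injury at 24 h after traumatic brain injury (TBI, 3 libraries). Per the labels' protocols, total RNA was fragmented, copied into double-stranded cDNA with 1 strand marked by deoxy-UTP, amplified by PCR and sequenced on an Illumina platform. The submitters' processing notes name TopHat2, an aligner of spliced reads, and the mouse build mm10; the counting tool, its strand setting, the read filters and the annotation release are not given in the sources used here. Per the file headers, the authors deposited a count and an RPKM value (counts scaled by row length and column total) for each of the 6 libraries, in a table of 56826 gene rows and a table of 64529 transcript rows. Of the gene rows, 23473 carry RefSeq gene names and 33353 carry identifiers of FANTOM3 cDNA clones.

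Several properties of the deposited counts and RPKM values were checked. RPKM equalled the deposited count divided by a fixed row length and the column total to within a relative spread of 6.06e-06. Rows overlap, so the same read can be counted in several rows, and column totals of 67252519 to 83929814 overstate the reads counted. Among counts from 1 to 20, 54.2% were even, and there were 10610 values of 2 against 7666 values of 1, the pattern that results where both mates of a read pair are counted. FANTOM3 clones inside exons of protein-coding genes had a median ratio to their host gene's RPKM of 0.702 on the same strand (3263 clones) and 0.305 on the opposite strand (120 clones). A gene and its antisense partner are therefore not treated as separable. Row starts equalled those of the GRCm38.p6 RefSeq annotation in 65.0% of rows matched by symbol, and ends in 64.4%. Coordinates are printed as the deposited table gives them. A total of 27 rows carry a date in place of a name, and 45 rows have no usable coordinates.

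Each named gene was given a class from the RefSeq table of GRCm38.p6, by symbol (21665 genes), accession (1682) or synonym (63), and 63 were left unmatched. This gave 20503 protein-coding genes and 1753 long non-coding RNA (lncRNA) genes. FANTOM3 rows were kept as a class of their own and placed against exons and gene bodies of protein-coding genes of GENCODE M21. A clone counts as sense exonic where at least 50% of its span lies in such exons, untranslated parts included, on the same strand.

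The planned test for FPKM-like values was replaced by the planned test for counts, because the tables hold counts. Gene and transcript counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10, minimum total 15), TMM normalization, no block and Benjamini-Hochberg adjustment over all rows tested; a row was called at an adjusted p under 0.05. Counts for mRNA and lncRNA genes are subsets of the gene fit. Isoform usage was tested with diffSplice of limma 3.58.1 on log2(RPKM + 1) of transcripts with a mean RPKM of at least 0.5. A set of 42 gene lists, fixed before the data were examined, was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 41 lists with at least 3 tested members, with an estimated correlation and fry as alternatives. Called lncRNA genes were compared with the nearest protein-coding gene within 100 kb by a two-sided permutation test with 100000 draws.

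Named genes were chosen by a rule also fixed before the data were examined. It takes the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes whose libraries do not overlap between groups and whose mean RPKM in the higher group is at least 2, the 5 lncRNA genes each way by the same rule, up to 4 called members of each list, 12 genes named in advance, 3 transcripts each way and the 3 genes with the smallest p for isoform usage. Genes named outside the rule are marked as chosen after their values were seen. Where a gene had 0 counts in all 3 control libraries, its fold is a lower bound against a floor of 3 counts over the control group; with 1 to 3 control counts the ratio carries a 95% exact counting interval. Intervals and floors cover counting error only, since PCR copies and mate reads are not independent molecules.

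The tests were tried on simulated data. On 42762 simulated gene rows for TBI against control, edgeR recovered 65 of 100 rows changed by 1 on the log2 scale and 91 of 94 changed by 2, and 12.8% of its calls were false, above the nominal 5%. On 49090 simulated transcript rows, 65 of 95 and 85 of 95 were recovered, and 7.98% of calls were false. Few of the simulated rows were changed, while 17.5% of the real gene rows were called. The false share of calls depends on how many rows change, so these shares may not hold for the real data. The isoform test recovered 197 of 200 changed genes among 3241, with 4 false calls. Its simulated transcripts varied independently, with 1 transcript of a changed gene moved by 1 on the log2(RPKM + 1) scale. Real transcripts of a gene share reads, so this recovery may not hold for the real data. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. Replicate pairs within a group correlated at 0.985 to 0.989 (Pearson, log2 CPM, across genes), and none agreed within sampling noise (chi-square per degree of freedom 7.76 to 19.0).

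Alternatives covered the low-count filter, scaling (DESeq2 1.42.0 median-of-ratios size factors, upper quartile), the test (DESeq2, limma-voom), a replicate block, stricter thresholds and leaving out each library. Leaving out FANTOM3 rows, testing the RPKM values with limma, counting FANTOM3 rows as lncRNA genes, and leaving out libraries in the comparison with neighbouring genes were chosen after seeing the data.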

Results

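RNA was sequenced from normal mouse cortex (3 control libraries) and from cortex around the injury focus at 24 h after traumatic brain injury (3 TBI libraries), to profile messenger RNA and lncRNA in injured tissue. Total counts over gene rows were 67252519, 74114630 and 83929814 in the control libraries and 71197218, 72169720 and 68808787 in the TBI libraries. The first principal component of log2 CPM (counts scaled by library size) held 58.9% of the variance and separated the groups. The second held 14.1%.

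In injured cortex many immune, reactive glial and stress-response genes were higher and many neuronal genes were lower. With an estimated correlation camera called 8 gene lists, all higher, and none of the neuronal lists. Of 15597 protein-coding genes tested, 2527 were higher and 1729 lower in TBI, and the rises were larger, with 1158 genes at least 2-fold higher against 131 at least 2-fold lower. Gfap, the intermediate filament of astrocytes, went from 21.2 ± 3.45 to 197 ± 21.6 RPKM (mean ± SD, n = 3 libraries per group, as for all RPKM values given this way), a log2 fold change of 3.13 ± 0.13 (SE; edgeR adjusted p = 2.28e-08). Hmox1, the inducible haem oxygenase, rose from 1.66 ± 0.154 to 63.7 ± 7.79 RPKM (log2 fold change 5.18 ± 0.12, edgeR adjusted p = 3.18e-10). P2ry12, a purinergic receptor of resting microglia, fell from 16.3 ± 0.466 to 4.69 ± 0.441 RPKM (log2 fold change -1.87 ± 0.09, edgeR adjusted p = 6.04e-08).

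The largest rises were in genes with almost no control counts. Mmp3, a matrix metalloproteinase on chromosome 9 (7445822 to 7455975), had 0 counts in the 3 control libraries and 226 to 1434 in the TBI libraries. With counts summed over each group it was at least 858-fold higher, a bound that need not hold for each TBI library. Il1rn, the interleukin 1 receptor antagonist, and the chemokine Cxcl2 were likewise at 0 in control and at least 507-fold and 488-fold higher over the summed counts. Without TBI replicate 3 the fitted log2 fold change was 12.12 in place of 12.75 for Mmp3 and 10.99 in place of 11.94 for Cxcl2, values that depend on the prior count. Tgm1, a transglutaminase, rose from 0.0369 ± 0.0186 to 19.6 ± 5.19 RPKM. Among the largest falls were Dio2, the deiodinase that activates thyroid hormone (29.8 ± 3.04 to 9.07 ± 0.923 RPKM), Nr4a1, an orphan nuclear receptor (16.6 ± 4.05 to 4.36 ± 2.20 RPKM), Hes5, a Notch target (4.89 ± 0.556 to 1.62 ± 0.265 RPKM), and Tcap (2.03 ± 0.401 to 0.493 ± 0.0844 RPKM). Over all 42762 gene rows tested, FANTOM3 clones included, 3900 were higher and 3576 lower.

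**Figure D1:**
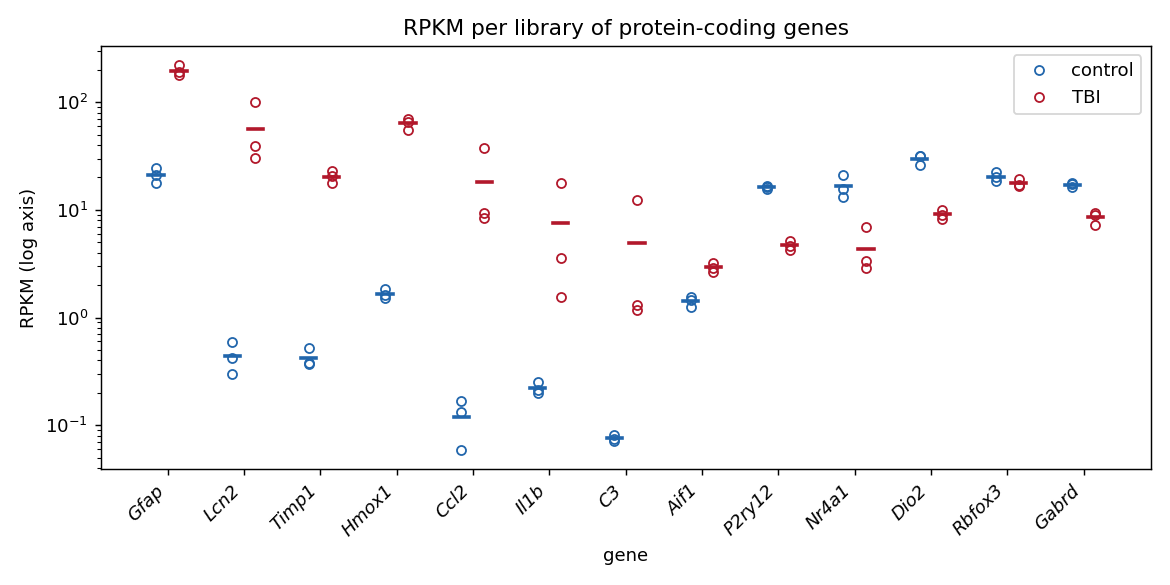
RPKM on a log axis for 13 protein-coding genes, with a circle for each library and a bar at the mean of the 3 libraries of a group. Il1b, C3 and Ccl2 reached 17.6, 12.3 and 37.3 RPKM in TBI replicate 3 and lay lower in the other TBI libraries, while Hmox1 and P2ry12 were close among replicates.

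Most tested genes of cytokines, chemokines and their receptors were higher. Of 17 tested cytokine and receptor genes, 16 were higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 2.42e-52, and adjusted p = 0.0314 with an estimated correlation). Tnf had 1 control count against 598 in TBI, a ratio of 601 (95% exact counting interval 107 to 23782). Its fitted log2 fold change of 8.79 became 8.08 without TBI replicate 3 and 10.65 without control replicate 2, which held the control count. Il1b rose from 0.222 ± 0.0293 to 7.57 ± 8.76 RPKM, and its log2 fold change of 5.01 became 3.43 without TBI replicate 3. The limma-voom test did not call Il1b (adjusted p = 0.0583, range over the alternatives 1.19e-07 to 0.0583). Il6 had a log2 fold change of 5.49, which became 4.67 without TBI replicate 3 and 6.79 without control replicate 2. Of 17 chemokines and receptors, 15 were higher and 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 1.54e-38, and adjusted p = 0.0675 with an estimated correlation). Ccl2, which attracts monocytes, rose from 0.120 ± 0.0549 to 18.3 ± 16.4 RPKM, with a log2 fold change of 7.20 that became 6.14 without TBI replicate 3.

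All 12 complement genes tested were higher (12 adjusted over the list alone, camera adjusted p = 3.93e-37, and adjusted p = 0.0269 with an estimated correlation). C4b rose from 2.15 ± 0.175 to 13.3 ± 1.23 RPKM and C3ar1, a complement receptor, from 0.479 ± 0.0487 to 5.28 ± 0.961. C3 had a log2 fold change of 5.95, which became 3.96 without TBI replicate 3, and limma-voom did not call it (adjusted p = 0.0537, range over the alternatives 6.09e-09 to 0.0537). All 15 interferon response genes were higher (15 adjusted over the list alone, camera adjusted p = 1.19e-17, and adjusted p = 0.137 with an estimated correlation), among them Ifitm3 (6.15 ± 0.0719 to 40.7 ± 12.4 RPKM) and the guanylate-binding protein Gbp2 (1.11 ± 0.243 to 11.3 ± 5.36 RPKM). In antigen presentation, 11 of 12 genes were higher (12 adjusted over the list alone, camera adjusted p = 2.14e-17, and adjusted p = 0.116 with an estimated correlation), including H2-Ab1 and Cd74 at log2 fold changes of 2.44 and 2.02. Of 14 inflammasome and cell death genes, 13 were higher (13 adjusted over the list alone, camera adjusted p = 8.64e-15, and adjusted p = 0.116 with an estimated correlation), including Ripk3, a kinase of necroptosis, at 3.03.

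Most tested markers of activated microglia and macrophages, infiltrating monocytes and macrophages, and neutrophils were also higher. Of 15 genes of activated microglia and macrophages, 13 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 7.36e-36, and adjusted p = 0.0269 with an estimated correlation). Msr1, a scavenger receptor, rose from 0.0644 ± 0.0148 to 8.01 ± 2.16 RPKM, Lgals3 from 0.149 ± 0.0353 to 9.33 ± 1.89, and Aif1, the gene of IBA1, from 1.42 ± 0.152 to 2.93 ± 0.294. Of 14 genes of infiltrating monocytes and macrophages, 13 were higher (13 adjusted over the list alone, camera adjusted p = 7.42e-43, and adjusted p = 0.0269 with an estimated correlation), with Arg1 going from 0.137 ± 0.063 to 11.4 ± 0.296 RPKM. Of 11 neutrophil genes, 9 were higher (9 adjusted over the list alone, camera adjusted p = 1.61e-20, and adjusted p = 0.0531 with an estimated correlation), and Cxcr2 rose from 0.0668 ± 0.027 to 2.43 ± 0.995 RPKM. Homeostatic microglia genes split, with 4 higher and 6 lower of 12 (4 and 6 adjusted over the list alone, camera adjusted p = 0.00773, and adjusted p = 0.121 with an estimated correlation). P2ry12 and Siglech fell by 1.87 and 1.72 on the log2 scale and Fcrls rose from 4.93 ± 0.327 to 10.4 ± 0.721 RPKM. With edgeR none of the 4 tested lymphocyte genes was called (0 adjusted over the list alone, camera adjusted p = 0.204), and most lymphocyte genes were too low to test.

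General astrocyte markers moved both ways, while all 13 pan-reactive astrocyte genes were higher (13 adjusted over the list alone, camera adjusted p = 5.18e-120, and adjusted p = 0.0269 with an estimated correlation). Lcn2, an iron-trafficking lipocalin, rose from 0.435 ± 0.144 to 56.4 ± 37.7 RPKM, and its log2 fold change of 6.91 became 6.21 without TBI replicate 3. Timp1, a metalloproteinase inhibitor, rose from 0.423 ± 0.0861 to 20.4 ± 2.43 RPKM. The list shares members with others that moved with it, Lcn2 with the neutrophil list and Timp1 with the extracellular matrix list, so these values do not belong to astrocytes alone. Of 14 astrocyte markers, 4 were higher and 2 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.682), with log2 fold changes of 0.59 for the water channel Aqp4 and -0.70 for the gap junction gene Gja1. Extracellular matrix and remodelling genes were higher for 16 and lower for 1 of 19 (16 and 3 adjusted over the list alone, camera adjusted p = 1.49e-59, and adjusted p = 0.0269 with an estimated correlation).

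Of the stress and repair lists, oxidative stress and regeneration genes were called higher with both the preset and an estimated correlation. Of 16 genes of oxidative stress and iron handling, 11 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 7.93e-27, and adjusted p = 0.0314 with an estimated correlation), and the metallothioneins Mt1 and Mt2 reached 568 ± 65.0 and 246 ± 41.6 RPKM. Of 12 regeneration-associated genes, 8 were higher and 1 lower (8 and 3 adjusted over the list alone, camera adjusted p = 2.13e-11, and adjusted p = 0.0269 with an estimated correlation), with the transcription factor Atf3 at a log2 fold change of 4.02 and Tubb6 at 3.17. Heat shock and unfolded protein genes gave 8 higher and 1 lower of 14 (9 and 1 adjusted over the list alone, camera adjusted p = 1.36e-06, and adjusted p = 0.121 with an estimated correlation), with Hspb1 at 3.33. Among p53 targets 6 of 10 were higher (6 adjusted over the list alone, camera adjusted p = 7.4e-07, and adjusted p = 0.130 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 1.60. Neurotrophic and growth factors gave 5 higher of 15 (5 adjusted over the list alone, camera adjusted p = 2.73e-05, and adjusted p = 0.121 with an estimated correlation), with Hbegf at 2.09 and Fgf2 at 2.36. Cell cycle genes gave 4 higher of 16 (5 adjusted over the list alone, camera adjusted p = 0.000989, and adjusted p = 0.270 with an estimated correlation), led by the replication helicase genes Mcm2 at 1.32 and Mcm6 at 1.24. Cholesterol synthesis gave 2 higher of 15 (1 adjusted over the list alone, camera adjusted p = 0.267). Immediate early genes moved both ways, with 2 higher and 5 lower of 14 (2 and 6 adjusted over the list alone, camera adjusted p = 0.805, direction up against a median of -0.44 and a mean of -0.14). The camera direction of this list was down without control replicate 2 (adjusted p = 0.828), without control replicate 3 (0.735), with a replicate block (0.0898) and without TBI replicate 1, where the list was called (adjusted p = 0.0332, range over the alternatives 0.0332 to 0.934). Atf3 and Jun were the higher members, and Nr4a1 fell by 2.01 on the log2 scale.

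**Figure D2:**
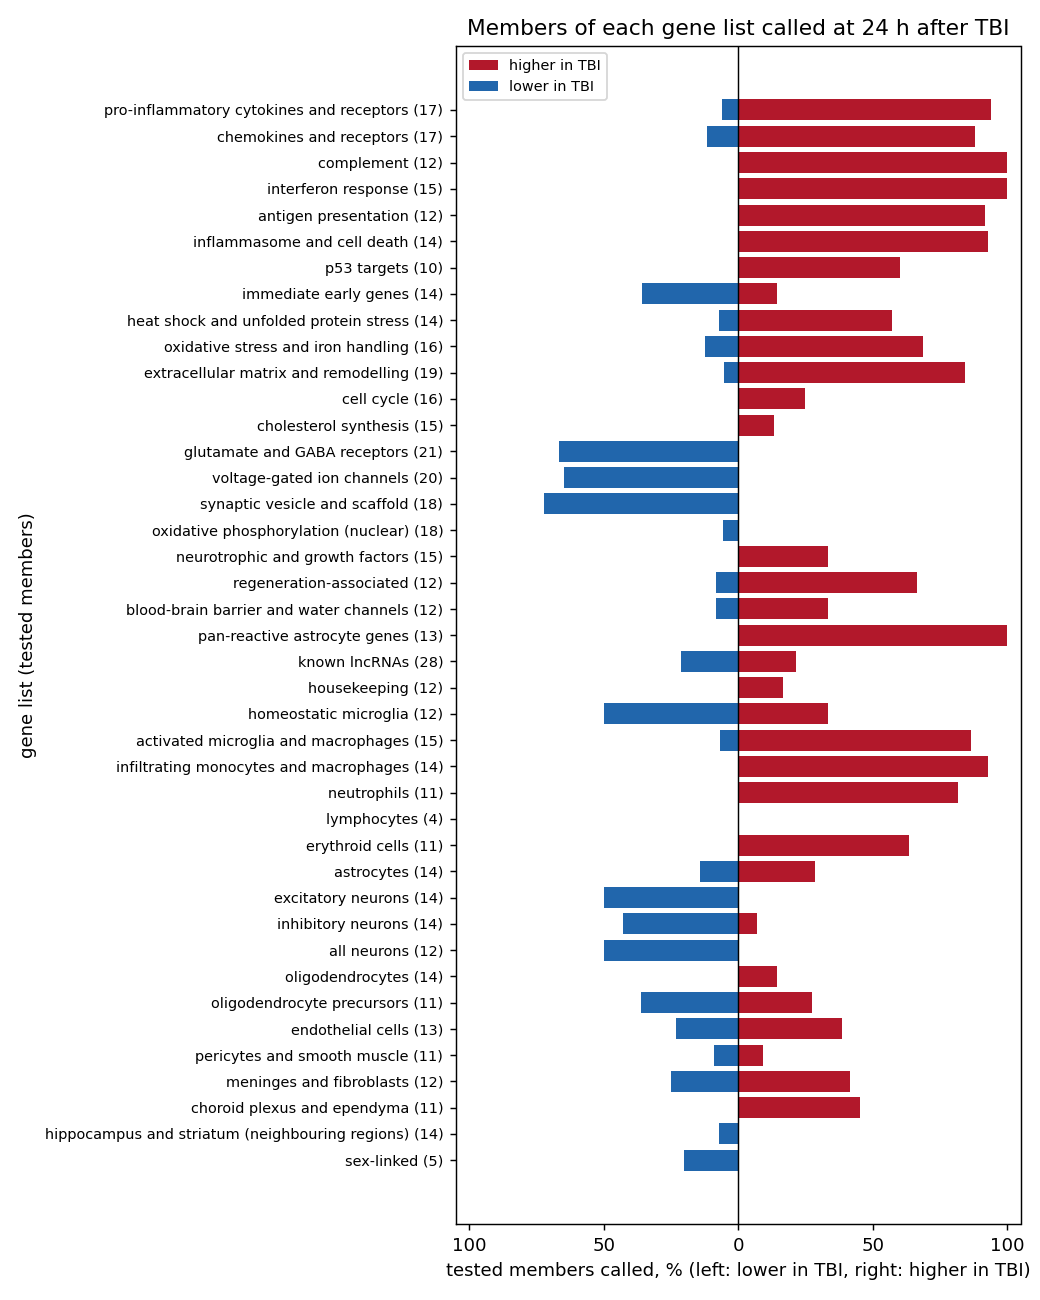
Percent of tested members of each gene list called higher (right) or lower (left) in TBI with edgeR at an adjusted p under 0.05, with the number tested in parentheses. All tested complement, interferon response and pan-reactive astrocyte genes lie to the right, and none of the 21 glutamate and GABA receptor genes does.

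Many neuronal genes were lower, and no neuronal list was called with an estimated correlation. Of 21 glutamate and GABA receptor genes, 14 were lower and 0 higher (17 lower adjusted over the list alone, camera adjusted p = 5.12e-13, and adjusted p = 0.0775 with an estimated correlation). Gabrd, an extrasynaptic GABA receptor subunit, fell from 17.1 ± 0.776 to 8.53 ± 1.15 RPKM. Voltage-gated ion channels gave 13 lower of 20 (14 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.59e-07, and adjusted p = 0.130 with an estimated correlation). Synaptic vesicle and scaffold genes gave 13 lower of 18 (13 adjusted over the list alone, camera adjusted p = 4.41e-08, and adjusted p = 0.135 with an estimated correlation), with Stx1a, a syntaxin of synaptic release, going from 62.2 ± 9.50 to 29.5 ± 1.85 RPKM. Markers of all neurons were lower for 6 of 12 (10 adjusted over the list alone, camera adjusted p = 7.53e-05, and adjusted p = 0.175 with an estimated correlation), with Tubb3 at a log2 fold change of -0.63 and Syt1 at -0.53. Rbfox3, the gene of the nuclear marker NeuN, was at 20.3 ± 2.02 and 17.8 ± 1.54 RPKM (edgeR adjusted p = 0.0659), and was not called. It was called without TBI replicate 1 (edgeR adjusted p = 0.0420), without a filter on low counts (0.0468), with FANTOM3 rows left out (0.0487), with a replicate block (0.0211) and with DESeq2 (adjusted p = 0.0437), in a range over the alternatives of 0.0211 to 0.248. Excitatory neuron markers were lower for 7 of 14 (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 7.53e-05, and adjusted p = 0.194 with an estimated correlation), with Tbr1 at -0.95. Inhibitory neuron markers were lower for 6 and higher for 1 of 14 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00156, and adjusted p = 0.130 with an estimated correlation), with Vip at -1.04. Nuclear genes of oxidative phosphorylation had 1 lower member of 18 (0 adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.617 with an estimated correlation), and the list's camera adjusted p was 0.0602 without control replicate 3 and 0.0635 without TBI replicate 3. Markers of the neighbouring hippocampus and striatum had 1 lower member of 14 (1 adjusted over the list alone, camera adjusted p = 0.810).

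Among other cell types, erythroid and choroid plexus markers had higher members and no lower ones, and oligodendrocyte precursor markers moved both ways. Oligodendrocyte markers gave 2 higher of 14 (2 adjusted over the list alone, camera adjusted p = 0.165), with transferrin, Trf, rising from 58.4 ± 10.9 to 223 ± 40.5 RPKM. Camera called the oligodendrocyte list higher without control replicate 1 (adjusted p = 0.00224), without TBI replicate 2 (0.0163) and with a replicate block (0.0296), and its direction was down without control replicate 2 (0.953, the upper end of the range over the alternatives). Oligodendrocyte precursor markers gave 3 higher and 4 lower of 11 (4 and 5 adjusted over the list alone, camera adjusted p = 0.254, direction down with a mean of -0.12 against a median of 0.0015), with Gpr17 at a log2 fold change of -1.04. Endothelial markers gave 5 higher and 3 lower of 13 (7 and 3 adjusted over the list alone, camera adjusted p = 0.00541, and adjusted p = 0.263 with an estimated correlation), with Vwf, the von Willebrand factor gene, at 1.82 and Itm2a at -1.15. Blood-brain barrier genes gave 4 higher and 1 lower of 12 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0176, and adjusted p = 0.270 with an estimated correlation), and the list's camera adjusted p was 0.101 without control replicate 2. Pericyte and smooth muscle markers gave 1 higher and 1 lower of 11 (3 and 3 adjusted over the list alone, camera adjusted p = 0.751). Meningeal and fibroblast markers gave 5 higher and 3 lower of 12 (6 and 5 adjusted over the list alone, camera adjusted p = 0.0261, and adjusted p = 0.479 with an estimated correlation), and the camera adjusted p was 0.0766, 0.360 and 0.192 without control replicate 1, control replicate 2 and TBI replicate 2. Erythroid genes gave 7 higher of 11 (8 adjusted over the list alone, camera adjusted p = 0.000109, and adjusted p = 0.263 with an estimated correlation), with Hba-a1 going from 56.3 ± 16.0 to 143 ± 50.7 RPKM; the globin genes share reads with near-identical copies and are uncertain singly. Choroid plexus and ependymal markers gave 5 higher of 11 (8 adjusted over the list alone, camera adjusted p = 2.02e-05, and adjusted p = 0.154 with an estimated correlation), with transthyretin, Ttr, going from 135 ± 43.2 to 427 ± 180 RPKM. Among 12 housekeeping genes 2 were higher, Actb and Gusb (2 adjusted over the list alone, camera adjusted p = 0.148). Among 5 sex-linked genes 1 was lower, Xist (1 adjusted over the list alone, camera adjusted p = 0.377). Xist was near the floor in every library, at 0.0415 to 0.0911 RPKM in control and 0.0240 to 0.0422 in TBI. Of the 41 lists tested, camera called 30 at the preset correlation and 8 with an estimated correlation. Fry called the housekeeping, lymphocyte and known lncRNA lists (adjusted p = 0.0307, 0.0187 and 0.00348), which camera did not, and did not call the lists of oxidative phosphorylation and of meninges and fibroblasts (adjusted p = 0.151 and 0.127).

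Long non-coding RNA genes changed in both directions. Of 941 lncRNA genes tested with edgeR, 57 were higher and 80 lower in TBI. At least 2-fold changes went the other way in balance, with 32 higher and 17 lower. Neat1, the scaffold RNA of nuclear paraspeckles (chromosome 19, 5842302 to 5845478), rose from 7.01 ± 0.432 to 23.1 ± 3.83 RPKM (log2 fold change 1.64 ± 0.11, edgeR adjusted p = 1.43e-06). Snhg1, a host gene of small nucleolar RNAs (chromosome 19, 8723487 to 8726326), rose from 5.88 ± 0.0461 to 13.9 ± 1.88 RPKM. F630028O10Rik on chromosome X (96239926 to 96243642) had the largest rise among the named lncRNA genes, from 0.105 ± 0.0234 to 2.30 ± 1.01 RPKM. G530011O06Rik and 1110038B12Rik were higher at log2 fold changes of 1.72 and 1.03. Gm11627 on chromosome 11 (102576399 to 102579119) fell from 2.20 ± 0.139 to 0.588 ± 0.218 RPKM, C730002L08Rik fell by 1.38 on the log2 scale, B230216N24Rik by 1.19, 4933439C10Rik by 1.07 and Dlx6as1, antisense to a homeobox gene of interneurons, by 0.96. G530011O06Rik overlaps Mid1, whose log2 fold change was 1.35. B230216N24Rik, 4933439C10Rik and Dlx6as1 overlap Pam, Zkscan17 and Dlx6. Those coding genes were at log2 fold changes of -0.33, -0.18 and -0.04, smaller falls than those of the lncRNA genes. Reads of these pairs are not separable. Malat1, the most abundant of the named lncRNA genes, was at 1460 ± 175 and 1680 ± 119 RPKM (edgeR adjusted p = 0.452), and Meg3 at 78.9 ± 10.4 and 77.4 ± 3.96 RPKM (edgeR adjusted p = 0.511). In the list of known lncRNAs, 6 were higher and 6 lower of 28 (6 and 7 adjusted over the list alone, camera adjusted p = 0.378). The count of called lncRNA genes was 89, 90 and 85 without control replicate 1, control replicate 3 and TBI replicate 3. Of 25821 FANTOM3 rows tested, 1287 were higher and 1759 lower; 6232 of them lie in coding exons of a gene on the same strand, where reads cannot be assigned to the clone alone.

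**Figure D3:**
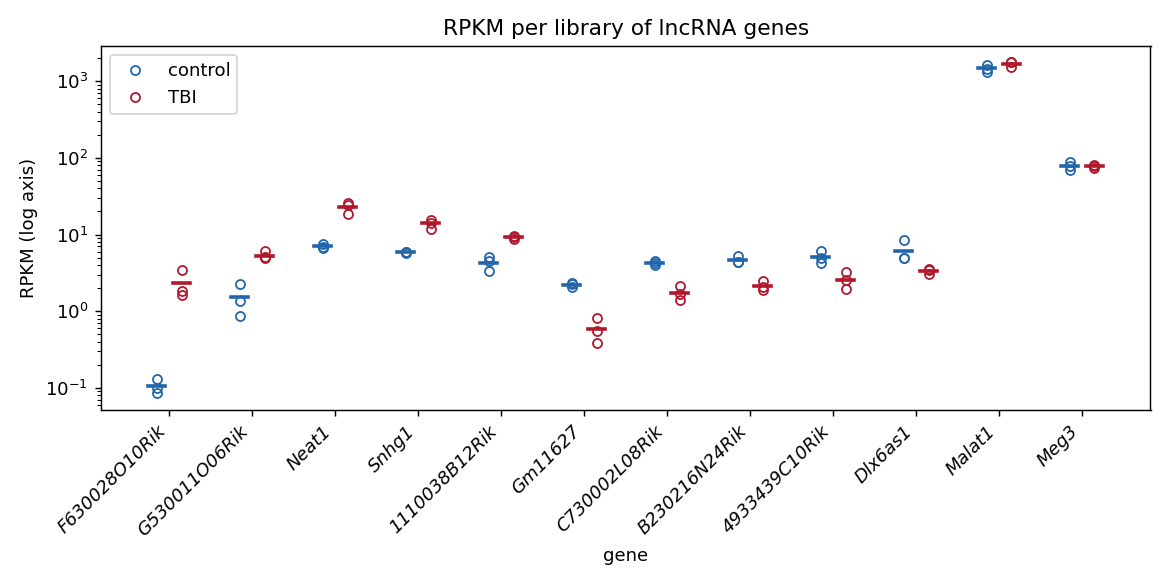
RPKM on a log axis for 12 lncRNA genes, with a circle for each library and a bar at the mean of the 3 libraries of a group. Neat1 and Snhg1 were higher in every TBI library, Gm11627 lower, and Malat1 and Meg3 overlapped between groups.

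Called lncRNA genes mostly shared the direction of the nearest protein-coding gene. A total of 122 called lncRNA genes had a tested protein-coding gene within 100 kb. Of these, 82.8% had a log2 fold change of the same sign as that gene, called or not, against 65.4% of all 878 tested pairs (two-sided permutation p = 2e-05). Most of the tested pairs hold lncRNA genes that were not called, whose signs are less certain. A higher share among called genes may partly follow from that, so the test does not show coupling of neighbours. Where gene bodies overlapped the share was 96.6% of 59 pairs, up to 10 kb apart it was 82.4% of 34, and from 10 to 100 kb it was 55.2% of 29, against 55.9% of all tested pairs at that distance. Snhg1 lies 118 bp from Slc3a2, whose log2 fold change was 0.66, and Neat1 lies 5496 bp from Frmd8 at 0.88. Gm11627, which fell by 1.97 on the log2 scale, lies 20241 bp from Gpatch8 at 0.02, the opposite sign. With overlapping pairs left out the share was 69.8% of 63 (two-sided permutation p = 0.0527), which is not past the threshold. The neighbouring genes were named after their values were seen.

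**Figure D4:**
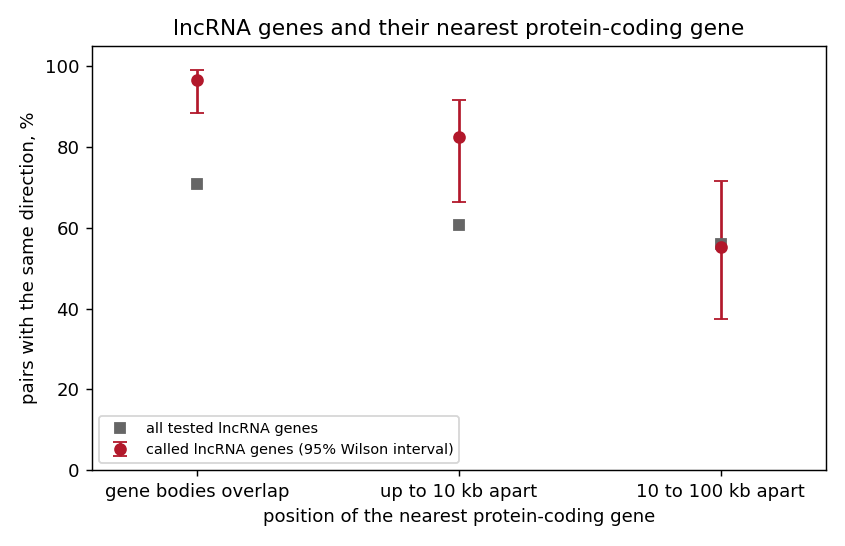
Percent of lncRNA genes whose nearest protein-coding gene, called or not, had a log2 fold change of the same sign, by distance. Red points with 95% Wilson intervals are called lncRNA genes and grey squares are all tested lncRNA genes; the called share is 96.6% for overlapping pairs and 55.2% from 10 to 100 kb.

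Transcripts also changed in both directions. Of 23269 RefSeq transcripts tested, 3685 were higher and 2915 lower; over all 49090 transcript rows, 4963 were higher and 4815 lower. The transcripts of Mmp3, Il1rn and Cxcl2 had the largest rises among those named and the transcripts of Nr4a1, P2ry12 and Dio2 the largest falls, at -2.02, -1.88 and -1.80 on the log2 scale. With limma diffSplice, 6 of 3241 genes were called for isoform usage. Only 33 were at an unadjusted p under 0.05, fewer than the 5% that no change would give, so the test is conservative here and the count does not bound how many genes changed. Among the 10 transcripts of Asph, an aspartate beta-hydroxylase gene, NM_001177856 went from 20.3 ± 0.608 to 12.3 ± 1.51 RPKM while NM_001177849 stayed at 6.04 ± 0.300 and 6.05 ± 0.255. In Lrrfip1, NM_001111311 went from 3.05 ± 0.140 to 5.96 ± 0.618 RPKM and NM_001111312 was at 9.68 ± 0.245 and 9.78 ± 0.754. In Dclk1, a doublecortin-like kinase gene, NM_001111051 fell by 0.62 on the log2 scale and NM_001195540 was at -0.15. The limma count was 2 without control replicate 1, 0 without control replicate 3 (31 genes at an unadjusted p under 0.05), 2 without TBI replicate 1, 3 without TBI replicate 2 and 1 without TBI replicate 3. Transcripts of a gene share reads, and in 46 tested genes all transcripts held identical counts.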

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

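Leaving out FANTOM3 rows, limma on RPKM, the wider lncRNA class and the libraries left out of the comparison with neighbouring genes were chosen after seeing the data. Of 163 named genes, 141 kept their direction and their side of the threshold in every alternative fit that tested them, and 0 changed direction. A gene that a fit left out was not counted as moved there, and the stricter thresholds were not applied to these genes. Calls with other filters, scalings and count tests shared 96.1% to 99.4% of the 7476 called gene rows, all in the same direction. The limma test on RPKM gave 6250 calls, 36.3% of them lower, and shared 68.2%. Leaving out FANTOM3 rows gave 5091 calls, which held 4340 of the 4430 calls on the rows kept, and 4904 protein-coding genes. Leaving out a library shared 68.9% to 86.0%. Gene rows, protein-coding genes, lncRNA genes and transcript rows past an absolute log2 fold change of 1 numbered 2138, 1289, 49 and 2600, and at an adjusted p under 0.01 they numbered 4164, 2616, 61 and 5477, by construction fewer. Counting intergenic and antisense FANTOM3 rows as lncRNA genes gave 931 calls, by construction more. An estimated inter-gene correlation called 8 lists against 30. The estimates reached 0.955 for the interferon response and 0.732 for chemokines, far above the preset 0.01. Homeostatic microglia, with an estimate of 0.0015, also lost the call, so higher correlations do not account for every loss. What else contributed was not tested. With overlapping pairs left out, the share of called lncRNA genes with the direction of their neighbour was 69.8% and no longer past the threshold (two-sided permutation p = 0.0527), and the cause was not tested.

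Leaving out each library in turn gave 5430 to 7902 gene rows, 3237 to 4553 protein-coding genes, 85 to 135 lncRNA genes, 7028 to 9934 transcript rows, 0 to 4 genes with changed isoform usage, 28 to 31 lists and a neighbour share of 75.3% to 83.0%, each on fewer libraries. Inflammatory folds such as those of Il1b and C3 were smaller without TBI replicate 3, and limma-voom did not call either (adjusted p = 0.0583 and 0.0537). Libraries with the same number in both groups had deviations that correlated weakly, at 0.0487 to 0.0546. Across the groups each library correlated best with its own number, a hint of pairing from the data and not the design. The replicate block gave 8259 gene rows, 4669 protein-coding genes, 156 lncRNA genes, 10599 transcript rows, 4 genes with changed isoform usage and 31 lists.

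Alternatives of the pseudocount for genes, transcripts and lists were not run, because they were planned for FPKM-like values and counts were tested. The prior count of the fitted folds was not varied. Depth limits the genes with few control counts, whose folds are bounds or wide intervals.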

Other observations

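Tests in this part were chosen after the results they bear on were seen. The exceptions are the camera tests of the neuronal lists, the counts of the real split and the test with overlapping pairs left out. Protein-coding genes were grouped by the letters their symbols start with, giving 199 families of at least 10 tested members. Of 49 genes whose symbols start with Rpl, most of them for proteins of the large ribosomal subunit, 33 were higher, at a median log2 fold change of 0.30. The alpha protocadherins, adhesion molecules of neurons expressed from 1 gene cluster with shared exons, were lower in 12 of 13 members (median -0.54), and since they share exons these are not independent. Toll-like receptor genes were higher in 8 of 11 (median 1.46) and annexins in 7 of 11 (median 0.65). The preset camera adjusted p was 5.65e-10 for Rpl, 7.69e-13 for Pcdha, 2.65e-14 for Tlr and 9.83e-11 for Anxa. None of the 199 families passed with an estimated correlation (lowest adjusted p = 0.353).

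For the 6 libraries there are 10 splits into groups of 3, too few for a share under 0.05. The real split was the 1 with the highest count in each case: 7476 gene rows, 4256 protein-coding genes, 137 lncRNA genes, 9778 transcript rows and 6 genes with changed isoform usage, where the highest of the other splits was 0 with edgeR or limma at an adjusted p under 0.05 (up to 1700, 641, 40, 1796 and 1 at an unadjusted p under 0.05). For gene lists the real split gave 30 and the highest other 25. Each other split sets 2 libraries of a condition against 1, so part of the difference between conditions stays in it. Its groups also mix conditions, which widens the spread within them. The counts of 0 therefore do not show how many calls no change would give.

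Neuronal markers had a median log2 fold change of -0.33 over 40 genes, and the 3 lists they come from were called lower at the preset correlation and not with an estimated correlation (camera adjusted p = 0.130 to 0.194). RNA of cells that entered the tissue may have diluted that of resident cells, which should lower the markers of other resident types as far. The neuronal median minus that of 74 markers of 6 such types was -0.31 (permutation p = 0.00206, over genes, which are not independent replicates). With homeostatic microglia left out it was -0.32 (permutation p = 0.001). The markers of those 5 types had a median of -0.004, and 50% had a negative log2 fold change, against 87.5% of the neuronal markers. For those 5 types these values argue against dilution as the only cause. Homeostatic microglia, at a median of -0.32, fell about as far as neurons. The markers of the 6 types went both ways with an SD of 0.66 over genes, and the highest median was 0.25 for endothelial cells. A contribution of dilution therefore stays open. A lower share of neurons may also contribute: it should raise the markers of the other types alike, and their highest and lowest medians lay 0.57 apart, which random lists also reach (permutation p = 0.274). A contribution of dilution, a lower share of neurons and lower transcription within neurons cannot be told apart here, because markers within each type moved both ways.

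Fewer rows were at 0 in TBI. Gene rows at 0 numbered 8235, 7422 and 7594 in control libraries and 5815, 5923 and 5880 in TBI libraries, and 315 rows were at 0 in every control library and counted in every TBI library against 30 the other way round. Depth does not account for it, since after thinning to the smallest total the groups differed by 1945 rows (SE 206). Traces of genomic DNA in the TBI libraries remain a candidate explanation: 263 to 285 of 1122 olfactory receptor genes had a count in TBI against 126 to 165 in control, while their summed counts differed less, 1389 to 1400 against 1002 to 1240. The share of counts on intronic and intergenic FANTOM3 rows changed by 0.0292 percentage points more than those receptors predict (SE 0.202), a spread too wide to decide, and RNA of cells that entered the tissue stays open and untested.

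Called lncRNA genes shared the direction of close coding genes. Reads shared with an overlapping gene alone predict no excess among pairs that do not overlap. Pairs up to 10 kb apart that do not overlap shared the direction in 82.4% against 60.6% of tested pairs (permutation p = 0.00692). That distance was set after the wider test over all 63 pairs that do not overlap had missed the threshold (69.8% against 58.7%, permutation p = 0.0527), so it is the more favourable of the tests run. Some of these pairs lie close, such as Snhg1 at 118 bp from Slc3a2, so reads may be shared beyond the deposited ends. Tested pairs also include lncRNA genes that were not called, whose signs are less certain. Shared reads therefore stay open. Transcription running into a close neighbour may contribute: pairs 10 to 100 kb apart shared it in 55.2% against 55.9% (permutation p = 1, 95% Wilson interval 37.5% to 71.6%). Shared regulation over short distances predicts the same and stays open.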
